A study of Rattus norvegicus with 4 samples.

How the data were processed

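Small RNA of 17 to 52 nt was size-selected from libraries made with 0.5 ug of total RNA and 12 PCR cycles, and was sequenced on a Genome Analyzer IIx, per the labels' protocols. The cells were rat aortic vascular smooth muscle cells grown with 10% FBS. The 4 libraries were grouped by the source label, 1 per group: control and Ang II (100 nM) for 1 h, 3 h and 24 h. The deposited files hold raw read counts of each distinct sequence (tag), with no header and no normalization. The submitters' processing notes name Novoalign and the genome build rn4, with no role for either. How reads were trimmed and filtered is not given in the sources used here. Tags are 16 to 42 nt long, so the longer part of the selected range appears cropped at 42 nt. A row that names no sequence held 7.07% of the control file's reads, 5.66% at 1 h, 5.13% at 3 h and 6.36% at 24 h, and was left out of all totals.

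No genome or miRNA annotation was used here. The miRNA names come from a list of 197 mature sequences written from general knowledge, not from a database or a genome match, when the files' first lines, totals and length distributions had been viewed but no counts of these sequences had. Of these, 155 are found exactly as tags, 165 have reads and 142 have at least 20. The 3' end of a listed sequence can differ from that of the reference, and reads from other loci with the same start cannot be excluded, so each name stands for the printed sequence. Of 177 hairpin names, 174 have a gene in a rat RefSeq table (assembly GRCr8), which was used for names alone. A tag was given to a miRNA if its first 18 nt were identical; where several listed sequences share these (12 sequences), the longest common start decided, and ties were shared equally. Fragments of tRNA, rRNA, U6 and Y1 were tags of at least 18 nt lying within 1 of 10 sequences written in the same way; 1 further sequence is not reported here and was left out of the totals and tests.

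The size rule, the lists and the rule for named miRNAs were fixed before the data were examined. They were written for miRNAs annotated by a reference and scaled to miRNA reads, with single tags by sequence and count where no annotation was given. None was used here, so the single tags are reported as planned, and the named sequences stand in for annotated miRNAs. The decision to lead with them, scaled to named miRNA reads, was made after per-miRNA ratios scaled to all deposited reads and the most read tags had been seen.

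A feature was called higher or lower if log2((RPM + 1)/(RPM + 1)) passed 1.5-fold with at least 100 reads in the higher of both libraries. Single tags and fragments of other RNAs were scaled to all deposited reads. No test of conditions was made. Counts have exact Poisson intervals, shares exact binomial (Clopper-Pearson) intervals and ratios exact conditional binomial intervals, all at 95% and all for counting error only, since PCR copies are not independent molecules. The rule for named miRNAs took the 10 largest rises and the 10 largest falls past the size rule at each time, all measured members of the miR-132/212, contractile and synthetic lists, and the 10 most abundant miRNAs. There were 25 lists, and a member was measured with 20 reads over the 4 libraries. Each list's median was placed among 10000 random lists of equal size matched on mean expression, which describes these libraries and is not a p-value. Shared-control values come from 100 Poisson simulations.

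Matching and calling were tested on simulated data first. All synthetic tags of the 197 sequences were matched to their miRNA, 0.816% of them as ties. These tags were trimmed or extended copies of the listed sequences, so a match was built in and checks the code alone. Misreads, other loci and errors in the list were not tested. In counts simulated for control and 1 h, control and 3 h, and control and 24 h, 20 miRNAs were made 2-fold higher and 20 lower among 116 with 100 reads, and 100 tags each among 4066, 4214 and 4200. All were recovered, but they were drawn from features with at least 300 expected reads, so recovery nearer the limit of 100 was not tested. Of unchanged features, 0 of 76 miRNAs passed 1.5-fold at each time, and 3 of 3866, 0 of 4014 and 5 of 4000 tags did; these simulations hold counting error alone.

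Alternatives were scaling to all deposited reads, TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios factors, other read minimums, a pseudocount of 10, a 2-fold limit, leaving out tied tags or tags read once, and merging tags by their first 18 nt. Chosen after seeing the data were counting the mature sequence alone (scaled to the sum of those reads), adding tags that start 1 or 2 nt further in, leaving out tags with an unread base or 12 nt of adapter, and the 1 h library as the reference. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.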

Results

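Small RNAs were sequenced from vascular smooth muscle cells of the rat aorta (Sprague-Dawley) that had been kept without serum for 48 h and then left untreated or given 100 nM angiotensin II (Ang II), a peptide hormone that raises blood pressure and acts on these cells. There were 4 libraries, 1 each for untreated control cells and for 1 h, 3 h and 24 h of Ang II, and the question was how the small RNAs at each time differed from the control. The control library held 14395539 reads that name a sequence, the 1 h library 13119417, the 3 h library 14370167 and the 24 h library 14534892. Reads that began like a known mature microRNA (miRNA) made up 69.7% of the control reads, 74.0% at 1 h, 75.5% at 3 h and 73.0% at 24 h. With 1 library per group there is no replicate check at any point below. The control carries no time, and no untreated library stands beside each time, so Ang II and time in culture cannot be told apart. Intervals are exact 95% intervals that cover counting error only, and miRNA levels (RPM) are scaled to the named miRNA reads of each library. Where the mature sequence alone is counted, the scale is the sum of those reads, and this change of scale moves ratios too. Names stand for the sequence printed with them and come from a list of published mature sequences written from general knowledge, and were not checked against an annotation of mature sequences here.

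The libraries were dominated by a few miRNAs. miR-143-3p (TGAGATGAAGCACTGTAGCTCA), a miRNA of contractile smooth muscle, held 355957 RPM in the control and 418601 RPM at 24 h. miR-21-5p (TAGCTTATCAGACTGATGTTGA), which is abundant in dividing smooth muscle cells, held 166340 RPM in the control, 161768 at 1 h, 181518 at 3 h and 199355 at 24 h. Next came let-7c-5p (TGAGGTAGTAGGTTGTATGGTT) with 112142 RPM in the control and 82774 RPM at 24 h. The other 7 of the 10 most abundant miRNAs were let-7a-5p (TGAGGTAGTAGGTTGTATAGTT), let-7b-5p (TGAGGTAGTAGGTTGTGTGGTT), let-7f-5p (TGAGGTAGTAGATTGTATAGTT), miR-10a-5p (TACCCTGTAGATCCGAATTTGTG), miR-24-3p (TGGCTCAGTTCAGCAGGAACAG), miR-30a-5p (TGTAAACATCCTCGACTGGAAG) and miR-99b-5p (CACCCGTAGAACCGACCTTGCG). Of these 10, miR-10a-5p at 24 h (fold 0.654, 0.650 to 0.658) was past 1.5-fold, and no other was at any time. That call was lost under the 3 other scalings (log2 ratio -0.35 with TMM factors). With the mature sequence alone miR-143-3p was past 1.5-fold at 24 h (log2 ratio 0.65), a call that rests on the change of scale. Tags that begin with that whole sequence held only 121310 of its 3572929 control reads.

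After 1 h of Ang II, 3 miRNAs were at least 1.5-fold higher than in the control and 2 were at least 1.5-fold lower, of 116 with 100 reads. miR-129-5p (CTTTTTGCGGTCTGGGCTTGC) was 2.55-fold higher (2.29 to 2.84), with 478 reads in the control and 1179 at 1 h. miR-21-3p (CAACAGCAGTCGATGGGCTGTC), the rarely kept arm of the miR-21 hairpin, was 2.38-fold higher (2.05 to 2.77), while miR-21-5p stood at 0.973 times the control (0.970 to 0.975). Under the 3 other scalings miR-21-5p lay above the control (log2 ratio 0.09 with TMM factors). miR-221-5p (ACCTGGCATACAATGTAGATTT) was 1.99-fold higher (1.83 to 2.16), against 0.821 (0.775 to 0.869) for miR-221-3p (AGCTACATTGTCTGCTGGGTTTC) of the same hairpin. miR-181a-5p (AACATTCAACGCTGTCGGTGAGT) was at 0.651 times the control (0.641 to 0.661) and miR-181b-5p (AACATTCATTGCTGTCGGTGGGT) at 0.633 (0.618 to 0.648). The 3 higher miRNAs were past 1.5-fold under every scaling tried, whereas with TMM or median-of-ratios factors 4 were higher and 0 lower (3 and 0 when scaled to all deposited reads), miR-181a-5p and miR-181b-5p having log2 ratios of -0.49 and -0.53 with TMM.

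After 3 h, 4 miRNAs were at least 1.5-fold higher and 4 at least 1.5-fold lower, of 117 with 100 reads. miR-132-3p (TAACAGTCTACAGCCATGGTCG), which is transcribed under the control of the cAMP-responsive factor CREB, was at 0.863 times the control at 1 h (0.755 to 0.986) and 2.31-fold higher at 3 h (2.08 to 2.58), with 491 reads in the control and 1229 at 3 h. miR-129-5p was 2.52-fold higher (2.27 to 2.81), miR-21-3p 2.34-fold (2.02 to 2.71) and miR-221-5p 2.25-fold (2.08 to 2.43). miR-181a-5p was at 0.493 times the control (0.485 to 0.501), miR-181b-5p at 0.523 (0.511 to 0.536), miR-423-3p (AGCTCGGTCTGAGGCCCCTCAGT) at 0.642 (0.597 to 0.689) and miR-10b-5p (TACCCTGTAGAACCGAATTTGTG) at 0.651 (0.645 to 0.658). With TMM or median-of-ratios factors, or scaled to all deposited reads, 6 miRNAs were higher and 2 lower, the 2 being miR-181a-5p and miR-181b-5p (log2 ratios -0.92 and -0.83 with TMM). Set against the 1 h library in place of the control, 1 miRNA was higher (miR-132-3p, log2 ratio 1.40) and 0 lower. When only tags identical to the listed mature sequence were counted, the log2 ratio of miR-221-5p at 3 h was 0.03 in place of 1.16, on 4 reads in the control and 4 at 3 h; its most read tag was a longer form (ACCTGGCATACAATGTAGATTTCTGT) with 480 reads in the control and 1579 at 3 h.

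**Figure D1:**
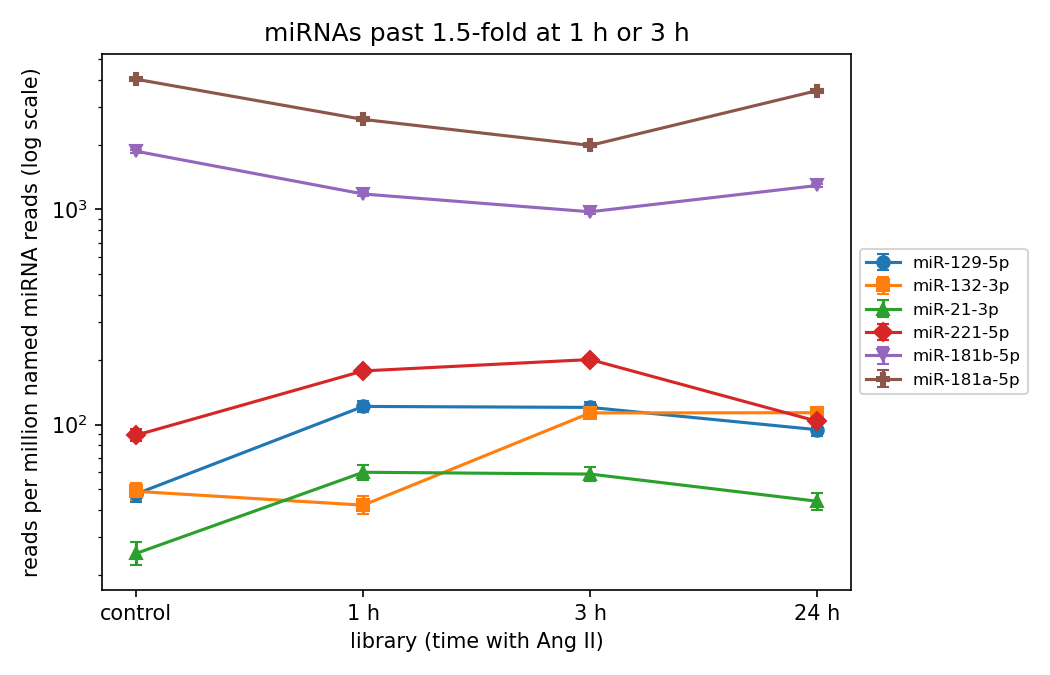
RPM scaled to named miRNA reads (log axis) of 6 miRNAs in the control, 1 h, 3 h and 24 h libraries, 1 library per point, with exact 95% Poisson intervals for counting error only. miR-129-5p, miR-21-3p and miR-221-5p are above the control at 1 h and 3 h, miR-132-3p from 3 h, and miR-181a-5p is lowest at 3 h.

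After 24 h, 6 miRNAs were at least 1.5-fold higher and 20 at least 1.5-fold lower, of 117 with 100 reads. miR-132-3p was 2.32-fold higher (2.09 to 2.58), as at 3 h, and miR-129-5p 1.99-fold (1.78 to 2.22). miR-21-3p was 1.75-fold higher (1.495 to 2.04), and miR-182-5p (TTTGGCAATGGTAGAACTCACACCG) and miR-183-5p (TATGGCACTGGTAGAATTCACT), whose genes lie in 1 cluster, were 1.75-fold (1.53 to 2.00) and 1.59-fold higher (1.26 to 2.01). miR-29b-3p (TAGCACCATTTGAAATCAGTGTT), which targets collagen and other matrix genes, was 1.53-fold higher (1.44 to 1.63). miR-221-5p stood at 1.16 times the control (1.06 to 1.27) and miR-181a-5p at 0.886 (0.873 to 0.898), the latter on the other side of the control with TMM factors (log2 ratio 0.09).

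The 20 lower miRNAs at 24 h included 10 members of 2 families that act on the cell cycle. miR-503-5p (TAGCAGCGGGAACAGTACTGCAG) had the lowest ratio, 0.315 (0.214 to 0.457), on 117 reads in the control and 39 at 24 h. It was followed by miR-497-5p (CAGCAGCACACTGTGGTTTGTA) at 0.494 (0.365 to 0.665), miR-351-5p (TCCCTGAGGAGCCCTTTGAGCCTGA) at 0.525 (0.455 to 0.605) and miR-93-5p (CAAAGTGCTGTTCGTGCAGGTAG) at 0.535 (0.525 to 0.545). The next 6 were miR-320-3p (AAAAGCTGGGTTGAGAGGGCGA), miR-342-3p (TCTCACACAGAAATCGCACCCGT), miR-18a-5p (TAAGGTGCATCTAGTGCAGATAG), miR-92a-3p (TATTGCACTTGTCCCGGCCTG), miR-15b-5p (TAGCAGCACATCATGGTTTACA) and miR-425-5p (AATGACACGATCACTCCCGTTGA), with ratios between 0.572 for miR-342-3p (0.502 to 0.650) and 0.613 for miR-425-5p (0.586 to 0.641). The median log2 ratio of the 117 miRNAs was -0.29 under this scaling, and TMM and median-of-ratios factors moved the ratios up by 0.26 and 0.30, which left 8 miRNAs higher and 4 lower (miR-503-5p, miR-497-5p, miR-351-5p and miR-93-5p). Scaled to all deposited reads, 6 were higher and 13 lower. Set against the 1 h library, 3 of the 6 were higher (miR-132-3p, miR-182-5p and miR-183-5p, log2 ratios 1.41, 0.61 and 0.81) and 9 miRNAs lower, 5 of them among the 20. Counting the mature sequence alone left 11 higher, 5 of them among the 6, and 3 lower, 2 of them among the 20. With a pseudocount of 10 RPM 5 of the 6 higher and 17 of the 20 lower remained, without miR-183-5p and miR-497-5p among others (log2 ratios 0.40 and -0.49).

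Among the lists of related miRNAs, the miR-17-92 cluster with its paralogs, which promotes proliferation, had 6 of 8 members with 100 reads at least 1.5-fold lower at 24 h. Its median log2 ratio was -0.63, at percentile 0.475 of 10000 random lists matched on expression, and was -0.37 with TMM factors. The miR-15/16 family, which restrains the cell cycle, had 4 of 7 such members lower, with a median of -0.68 at percentile 0.12 and of -0.44 with TMM factors. These counts were 1 of 8 and 2 of 7 with TMM factors, and 5 of 8 and 3 of 7 with a pseudocount of 10 RPM. At 1 h and 3 h the medians were -0.10 and -0.03 for miR-17-92 and -0.13 and -0.04 for miR-15/16, with no member of 100 reads past 1.5-fold, and with TMM factors they changed sign for miR-17-92 (0.03 and 0.07) and at 3 h for miR-15/16 (0.06). At 3 h both were also above 0 with median-of-ratios factors (0.13 and 0.12) and scaled to all deposited reads (0.08 and 0.07). In the miR-15/16 list miR-195-5p (TAGCAGCACAGAAATATTGGC) was not among the lower miRNAs, with 93 reads in the control and 104 at 24 h.

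**Figure D2:**
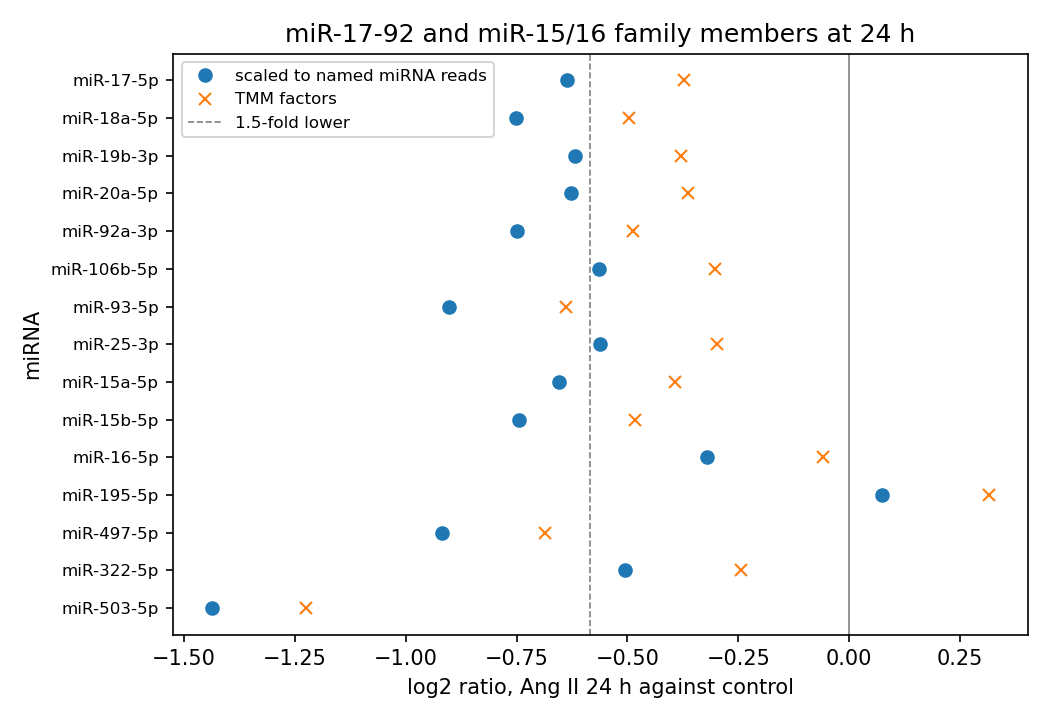
Log2 ratios at 24 h against control for the 15 members of the miR-17-92 and miR-15/16 lists with 100 reads, scaled to named miRNA reads (circles) or with TMM factors (crosses); the dashed line marks 1.5-fold lower. With TMM factors miR-93-5p, miR-497-5p and miR-503-5p stay beyond the line, and miR-195-5p lies above 0 under both.

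The miR-132/212 list, regulated through CREB, had median log2 ratios of 0.25 at 1 h, 0.99 at 3 h and 0.94 at 24 h, at percentiles 91.98, 99.9 and 99.98. With a pseudocount of 10 RPM these medians were 0.06, 0.29 and 0.28, and with the mature sequence alone 0.94, 1.71 and 1.68. miR-132-3p was its single member with 100 reads, and the others had few: miR-212-3p (TAACAGTCTCCAGTCACGGCCA) went from 28 reads in the control to 60 at 3 h and 75 at 24 h, miR-212-5p (ACCTTGGCTCTAGACTGCTTACT) from 5 to 32 and 17, and miR-132-5p (ACCGTGGCTTTCGATTGTTACT) from 9 to 16 and 16. The list of early serum-response miRNAs, which shares miR-132, miR-212 and miR-21 with other lists, had medians of 0.09, 0.25 and 0.33, at percentiles 90.2, 99.9 and 99.985. Its medians were 0.20, 0.33 and 0.55 with TMM factors and 0.04, 0.10 and 0.14 with a pseudocount of 10 RPM. With the mature sequence alone they were 0.18, 0.74 and 0.76.

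Of the contractile list, 0 of 5 measured members were past 1.5-fold at 1 h, 3 h or 24 h, although miR-143-3p was at 24 h with the mature sequence alone (log2 ratio 0.65). miR-143-3p stood at 1.15 (1.147 to 1.151), 1.15 (1.151 to 1.154) and 1.18 (1.174 to 1.178) times the control at 1 h, 3 h and 24 h, and miR-145-5p (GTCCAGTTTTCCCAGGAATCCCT) at 1.00, 0.899 and 1.03. miR-143-5p (GGTGCAGTGCTGCATCTCTGG), miR-145-3p (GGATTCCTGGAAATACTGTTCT) and miR-1-3p (TGGAATGTAAAGAAGTGTGTAT) had log2 ratios from -0.40 to 0.22. The list's medians were -0.11, -0.25 and 0.05, at percentiles 70.5, 27.3 and 96.4, and with TMM factors they were 0.02, -0.15 and 0.31. The synthetic list, of miRNAs linked to proliferating smooth muscle, had 9 measured members and medians of 0.14, 0.07 and 0.16, at percentiles 99.7, 99.3 and 99.9. With TMM factors these medians were 0.27, 0.17 and 0.42. Its members past 1.5-fold were the minor arms miR-21-3p and miR-221-5p, while miR-222-3p (AGCTACATCTGGCTACTGGGTCT) stood at 0.785, 0.839 and 1.05 times the control. With the mature sequence alone counted, miR-221-3p and miR-222-3p were also past 1.5-fold at 24 h (log2 ratios 0.78 and 0.77). Part of such rises comes from the change of scale. The log2 ratio of let-7a-5p at 24 h went from -0.32 to -0.05 in that setting. Yet its mature tag made up 82.3% of its reads in the control and 81.1% at 24 h. Taking away a shift of that size leaves miR-221-3p, miR-222-3p and miR-143-3p above the control at 24 h, but below 1.5-fold. Their calls in that setting thus rest on the change of scale. miR-146a-5p (TGAGAACTGAATTCCATGGGTT) stood at 1.07, 0.792 and 1.12, miR-26a-5p (TTCAAGTAATCCAGGATAGGCT) at 1.10, 1.05 and 0.943, and miR-31-5p (AGGCAAGATGCTGGCATAGCTG) at 1.23, 1.13 and 0.797. Of the miR-31-5p reads, 16.03% in the control, 41.5% at 1 h, 31.2% at 3 h and 8.42% at 24 h came from tags of 30 nt or more, so its level is not that of the mature form alone. Counting the mature sequence alone, miR-31-5p had log2 ratios of -0.02, 0.14 and 0.29, above the control at 24 h where all tags lay below it. Since the scale changed as well, this turn at 24 h cannot be put down to the long tags. Taking away a shift of the size seen for let-7a-5p leaves the mature miR-31-5p sequence near the control at 24 h.

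The remaining lists held few calls. Medians at 1 h, 3 h and 24 h were -0.13, -0.19 and -0.32 for let-7, 0.05, -0.12 and -0.22 for miR-30, 0.03, -0.04 and -0.11 for miR-23/27/24, and -0.15, 0.08 and 0.04 for miR-34, with no member of 100 reads past 1.5-fold. They were -0.11, -0.18 and -0.21 for the inflammatory NF-kB list, -0.34, -0.25 and -0.32 for miR-199a with miR-214, and -0.37, -0.37 and -0.39 for miR-99a, miR-99b, miR-100, miR-125a and miR-125b together, again with no member past 1.5-fold. The miR-29 list had -0.0017, 0.22 and 0.16, with miR-29b-3p higher at 24 h. The Hox cluster miRNAs had -0.39, -0.46 and -0.48, with 1 of 3 members lower at 3 h (miR-10b-5p) and 1 at 24 h (miR-10a-5p), neither of them under the 3 other scalings (log2 ratios -0.52 and -0.35 with TMM factors). The list of miR-320 and miR-484, whose hairpins are made without the usual nuclear cut, had -0.31, -0.22 and -0.60, with miR-320-3p lower at 24 h. The hypoxia miRNA miR-210-3p (CTGTGCGTGTGACAGCGGCTGA) had log2 ratios of 0.01, -0.45 and -0.0016. Of the imprinted Dlk1-Dio3 cluster 1 of 36 arms was measured (miR-379-5p, TGGTAGACTATGGAACGTAGG, with 11, 12, 10 and 15 reads), and none of the 3 arms of the Igf2/H19 list. With TMM factors 12 of 60 list medians changed sign, among them at 1 h let-7 (0.0048), NF-kB (0.02) and miR-29 (0.12), miR-30 at 24 h (0.04), and miR-23/27/24 at 3 h and 24 h (0.06 and 0.15). The medians of the Hox list, of miR-199a with miR-214, of the miR-99 and miR-125 miRNAs and of miR-320 with miR-484 stayed below 0 under all 3 other scalings. With the mature sequence alone those of miR-199a with miR-214 (0.014 and 0.20) and of miR-320 with miR-484 (0.060 and 0.0039) were above 0 at 3 h and 24 h.

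Markers of other cell types were mostly at few reads. The endothelial miR-126-3p (TCGTACCGTGAGTAATAATGCG) had 1592 reads in the control and 1326, 1650 and 1400 at 1 h, 3 h and 24 h, and its list had medians of 0.01, -0.01 and -0.24 (0.14, 0.08 and 0.01 with TMM factors). In the blood and immune list 1 of 7 arms was measured (miR-150-5p, TCTCCCAACCCTTGTACCAGTG, with 31, 34, 34 and 44 reads). The epithelial list had medians of 0.06, -0.28 and -0.35, its most read member being miR-200c-3p (TAATACTGCCGGGTAATGATGGA) with 51 reads in the control and 76, 46 and 53 at 1 h, 3 h and 24 h. The striated muscle list had -0.25, -0.40 and -0.46 and was led by miR-1-3p. The neural list had -0.35, -0.08 and -0.28, and its member miR-129-5p had the highest ratio of the miRNAs with 100 reads at 1 h and 3 h, while miR-9-5p (TCTTTGGTTATCTAGCTGTATGA) went from 630 reads to 414, 504 and 472. In the liver and endocrine list miR-7a-5p (TGGAAGACTAGTGATTTTGTTGT) was measured, with 282 reads in the control and 336, 451 and 355 with Ang II.

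The ratios at the 3 times share 1 control library. Across 117 miRNAs, which are not independent replicates, the log2 ratios at 1 h and 3 h had a correlation of 0.82, against 0.53 in 100 simulations of unchanged libraries, with covariances of 0.096 and 0.0022. For 1 h and 24 h the correlation was 0.52 against 0.51 (covariances 0.068 and 0.0021), and for 3 h and 24 h 0.61 against 0.52 (0.091 and 0.0022). All 3 miRNAs higher at 1 h were also higher at 3 h, where independent lists would share 0.103, and 3 of the 4 higher at 3 h were higher at 24 h, where they would share 0.205. For 1 h and 24 h 2 higher miRNAs were shared (0.155 if independent), and both miRNAs lower at 1 h were lower at 3 h (0.0690). Of the 4 lower at 3 h, 0 were among the 20 lower at 24 h, where independent lists would share 0.684. The simulations hold counting error alone, and the values for independent lists leave the shared control out. The control cannot be split, so part or all of the excess may come from the shared control.

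Among pairs of arms whose minor arm had 100 reads, the ratio of minor to major arm moved most for miR-221 and miR-21 at 1 h and 3 h. miR-221-5p made up 25.05% of the miR-221 reads in the control, 44.7% at 1 h, 46.6% at 3 h and 25.7% at 24 h. miR-21-3p made up 0.0152% of the miR-21 reads in the control, 0.0371% at 1 h, 0.0324% at 3 h and 0.0221% at 24 h. On few reads, miR-212-5p went from 15.2% of the miR-212 reads in the control (5 reads) to 34.8% at 3 h (32 reads). Over 84 miRNAs with 1000 reads in every library, the median change in mean tag length was 0.00925, 0.00112 and -0.0310 nt at 1 h, 3 h and 24 h, with the largest changes in miR-31-5p (3.42, 1.99 and -1.22 nt). Though these medians were small, mean length was below the control for 23 of the 84 at 1 h, 41 at 3 h and 70 at 24 h. Of longer miR-143-3p tags that begin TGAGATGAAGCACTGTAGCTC, the share with T as the next base was 89.5% in the control, 89.4% at 1 h, 89.5% at 3 h and 89.1% at 24 h.

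Fragments of other RNAs also differed at 24 h. The 5' fragments of tRNA-Gly (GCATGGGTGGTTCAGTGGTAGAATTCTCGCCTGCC and shorter tags within it) went from 936 RPM of all deposited reads in the control to 800 at 1 h, 666 at 3 h and 2547 at 24 h, 2.72-fold (2.67 to 2.77). A second tRNA-Gly sequence (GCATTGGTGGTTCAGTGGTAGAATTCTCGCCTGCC) went from 224 to 208, 183 and 436, 1.94-fold at 24 h (1.86 to 2.03). Both tRNA-Gly sequences differ at a single base, and a tag within both was counted under each. Their values thus overlap, and neither fold is that of the sequence's own tags alone. Those of tRNA-Asp had log2 ratios of -0.54, -1.08 and 0.49. At 24 h tRNA-Lys, tRNA-Val and tRNA-His lay nearer the control, with log2 ratios of -0.18, -0.04 and 0.18. With each tag counted once, the 6 tRNA sequences together took 0.169% of control reads (0.167% to 0.171%) and 0.363% of reads at 24 h (0.360% to 0.366%). Fragments of the 5.8S ribosomal RNA had log2 ratios of -0.27, -0.64 and -0.67, those of the 5S ribosomal RNA -0.09, -0.19 and -0.17, those of U6 -0.40, -0.46 and -0.67, and those of the Y1 RNA -0.16, -0.21 and 0.02.

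**Figure D3:**
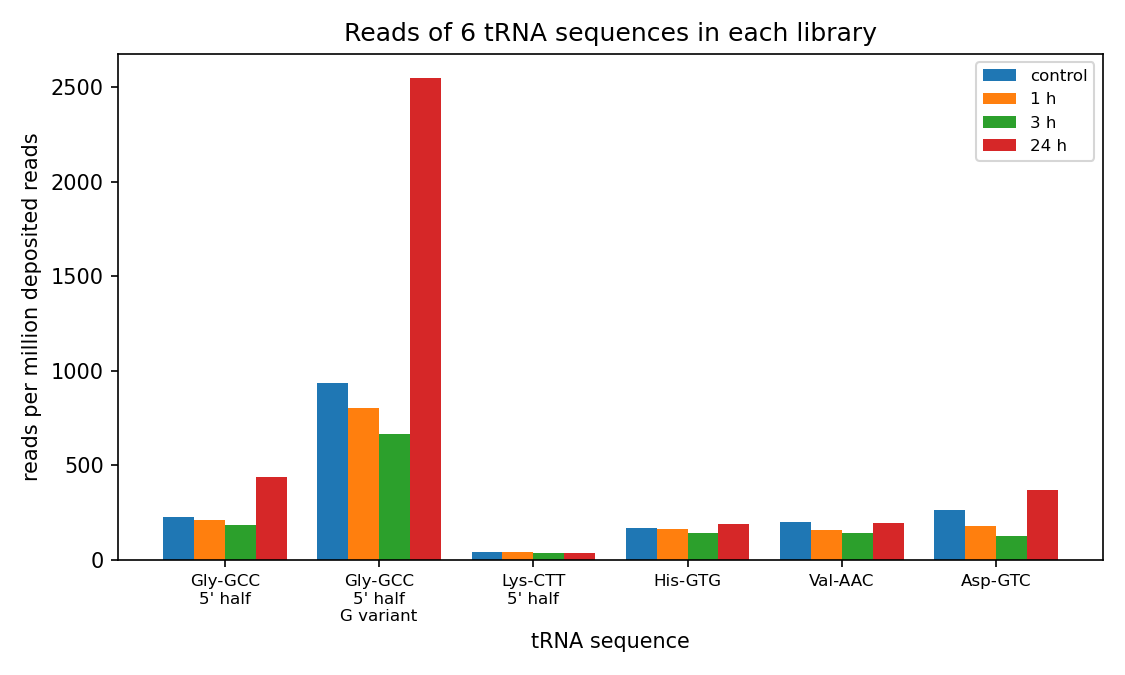
RPM of all deposited reads (linear axis from 0) of 6 tRNA sequences in each of the 4 libraries, 1 bar per library. The tRNA-Gly G variant reaches 2547 at 24 h against 936 in the control. A tag within both tRNA-Gly sequences is counted in each.

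Tag by tag and scaled to all deposited reads, 217 tags were at least 1.5-fold higher and 776 lower at 1 h, of 4527 with 100 reads. At 3 h the numbers were 263 and 1081 of 4636, and at 24 h 652 and 1163 of 4939. With TMM factors they were 363 and 516, 450 and 786, and 862 and 823. The most read tag outside the named miRNAs, AGCCTGTGATGAATTCAATTTCTGAC, had 214818 reads in the control and stood at 0.697, 0.727 and 0.497 times the control at 1 h, 3 h and 24 h. A 41-nt tag, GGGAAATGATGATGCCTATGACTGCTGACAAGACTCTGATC, with 69457 reads in the control, stood at 0.462, 0.651 and 0.520. Both were singled out after their values were seen. Read quality differed between the libraries: 0.352% of control reads held an unread base, against 0.136%, 0.127% and 0.155% at 1 h, 3 h and 24 h, and in the control 59.1% of these had it at nt 24.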

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

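All tests in this part were chosen after the results were seen. No outlier among samples can be looked for with 1 library per group.

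Reads of the tRNA sequences made up 0.363% of the 24 h library, above the 0.169% of the control (0.167% to 0.171%), and lie outside the miRNA comparison. A general breakdown of RNA in the 24 h library would raise fragments of other RNAs as well. Over the 8 sequences other than tRNA-Gly from tRNA, rRNA, U6 and Y1 the upper quartile of the 24 h log2 ratios was 0.056, so these were not raised as a set. Its rRNA part was 5.8S and 5S alone, so the set cannot speak to breakdown of RNAs outside it, which is not decided here. It stays open for tRNA-Asp (log2 ratio 0.49) and for short tags outside that set, such as 17-nt AGAACGCAGCTAGCTGC within the 5.8S ribosomal RNA, with 18 reads in the control and 1000 at 24 h. Reads of 16 to 19 nt made up 3.68% of the control, 3.41% at 1 h, 3.50% at 3 h and 3.99% at 24 h. Mean tag length was below the control for 70 of 84 miRNAs at 24 h. Both go in the direction of breakdown at 24 h, without deciding it. An effect of Ang II, time in culture and a difference between single libraries stay open and untested, since each time has 1 library and no untreated library of its own.

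A 36-nt tag that starts as miR-31-5p and runs 14 nt further (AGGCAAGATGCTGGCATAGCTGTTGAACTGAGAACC) had log2 ratios of 1.77 at 1 h and 1.34 at 3 h and of -0.99 at 24 h, with 626 reads in the control and 1974, 1599 and 312 with Ang II, in opposite directions; the difference was not tested.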

How the results depend on the processing

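The alternatives that count the mature sequence alone, shift the start, leave out unread bases or adapter, or take the 1 h library as reference were chosen after seeing the data. The causes of the changes below were not tested, except where a stricter limit removes features by construction. TMM factors moved miRNA log2 ratios by 0.13, 0.10 and 0.26 at 1 h, 3 h and 24 h, and median-of-ratios factors by 0.15, 0.16 and 0.30. Of 2 lower miRNAs at 1 h, 0 remained with all deposited reads, TMM, median of ratios, a 2-fold limit or the mature sequence alone. Of 4 lower at 3 h, 2 remained with each of the 3 scalings and 1 at 2-fold. At 3 h 8 were higher with a minimum of 20 reads and 7 with the mature sequence alone (3 shared with the main 4); against the 1 h library 1 was higher and 0 lower. Of 20 lower at 24 h, 13 remained with all deposited reads, 4 with TMM, 4 with median of ratios and 1 at 2-fold; the mature sequence alone gave 3 (2 shared) and the 1 h reference 9 (5 shared). Of 6 higher at 24 h, 1 remained at 2-fold and 3 with the 1 h reference; the mature sequence alone gave 11 (5 shared). Under the 3 other scalings all main higher miRNAs remained at each time. For tags, TMM gave 363 higher and 516 lower at 1 h and 450 higher at 3 h. A minimum of 500 reads gave 51 and 160 at 1 h, 57 and 238 at 3 h and 134 and 287 at 24 h. Merging by 18 nt gave 121 higher and 684 lower at 3 h and 669 lower at 24 h. With the 1 h reference, 526 were lower at 3 h and 706 at 24 h. The other counts stayed within 1.5 times. Of 35 named log2 ratios past 1.5-fold, whatever their reads, 24 stayed so with TMM, 24 with median of ratios, 24 with the mature sequence alone, 30 with all deposited reads and 28 with a pseudocount of 10, and none changed sign among called values. Of all 129 named log2 ratios, 15 changed sign with TMM, 17 with median of ratios, 21 with the mature sequence alone and 7 with all deposited reads. Restricting tags to an annotated 5' end and adding untemplated 3' bases were not run, since both need an annotated hairpin. No paired analysis was possible because each group has 1 library.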

Other observations

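The tests on the minor arms and on length variants in the miRNA families were chosen after the result was seen. So was the test on GC content, in place of an earlier fit that moved nothing. The test on abundance was chosen after the families' low ratios had been seen, but before its own value had.

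Tags longer than a mature miRNA held patterns of their own, and the tags in this paragraph were singled out after their values were seen. A 42-nt tag made of miR-22-3p (AAGCTGCCAGTTGAAGAACTGT) followed by the start of miR-21-5p (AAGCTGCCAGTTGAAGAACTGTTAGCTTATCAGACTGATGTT) had 1236 reads in the control, 799 at 1 h, 1578 at 3 h and 1489 at 24 h. Tags of 30 nt or more made up 6.83% of miR-22-3p reads in the control and 10.1% at 3 h. Most of these reads were that join, with 1236 of 1405 in the control and 1578 of 1760 at 3 h. How the join arose was not tested, so it is not shown to be an RNA of the cells. A 34-nt tag that starts as miR-143-5p (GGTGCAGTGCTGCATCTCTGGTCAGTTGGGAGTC) had 557 reads in the control and 887 at 24 h, 1.58-fold (1.42 to 1.76). Among tags outside the named miRNAs, 17-nt CGGACCAGGGGAATCCG had 0 reads in the control, 1 at 1 h, 1 at 3 h and 531 at 24 h, and 19-nt CCGGTGAGCTCTCGCTGGC had 57, 51, 47 and 1379.

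The minor arms miR-21-3p and miR-221-5p had higher ratios to the control than their partner arms at 1 h and 3 h. A shift of minor arms as a class is argued against by the other 10 pairs with 100 reads, whose upper quartile of the log2 difference was 0.023 at most. Of these, miR-22 (0.57 and 0.43 at 1 h and 3 h) and miR-126 (0.46 at 1 h) went the same way, but stayed below the lowest difference of miR-21 and miR-221, 1.07. Trimmed or misread tags are argued against by the most read tag of each arm alone, whose lower counting bound on the log2 scale at both times was at least 1.32 for miR-21-3p and 1.24 for miR-221-5p. For miR-221-5p this tag is a 26-nt form, and the listed 22-nt sequence, with 4 reads in the control and 4 at 3 h, decides nothing. An effect of Ang II, time in culture and a difference between single libraries stay open and untested, since neither replicates nor a time-matched control separate them.

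The miR-17-92 and miR-15/16 families lay below other miRNAs at 24 h, with a median log2 difference of -0.40 (bootstrap interval over 17 members -0.51 to -0.33). Both lists were singled out for their low medians, and members of a cluster are not independent. The bootstrap intervals here thus describe the spread of members in 1 pair of libraries and can be too narrow. Over the other measured miRNAs the correlation of the log2 ratio with GC content was -0.026, and that trend would shift the families by 0.0025 (bootstrap interval -0.015 to 0.019), which argues against it as the whole cause. With abundance the correlation was -0.20, and after a straight-line fit on it the families' median residual was -0.49 (-0.64 to -0.39). That residual is taken from a least-squares line, not from the other miRNAs' median, so it is not a larger difference than -0.40. The fit on GC content, with almost no slope, left -0.49 as well. The fit on abundance thus moved the families little, which argues against that trend as the whole cause. With the mature sequence alone counted the difference was -0.43 (-0.56 to -0.30), which argues against length variants. A single scaling factor cannot change this relative position, though it sets how many members pass 1.5-fold. An effect of Ang II on these families, time in culture and a difference between libraries stay open, since neither replicates nor a time-matched control separate them.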
